A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

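RNA sequencing gave 9 libraries of Saccharomyces cerevisiae grown exponentially in synthetic SD medium. The labels describe 3 strains in a background lacking functional HIS3, LEU2, MET15 and URA3, with 3 repeats each. The control strain carries the nourseothricin-resistance marker at the HO locus. In the overexpression strain the marker and a TEF promoter stand before YET3, and in the deletion strain the marker replaces YET3. The labels call the libraries repeats without saying whether they came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

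The authors deposited one table per library with a whole-number count for each open reading frame, and the counts sum to a different total in each library. Per the submitters' processing notes, cutadapt, UMI-tools and genome build R64 were used. The aligner, the counting window, the use of strand and the treatment of reads shared between genes are not given in the sources used here. Whether the counts are of molecules or of reads is not given either, so intervals and floors cover counting error only. Reads of a gene and an overlapping antisense gene cannot be told apart, and rows of near-identical gene families are uncertain for the same reason.

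Each table held 6631 rows. The last 2 rows repeated the identifiers of HTB2 and HHT2 with other counts. The first occurrence was kept and the 2 appended rows were left out, which removed between 0.0372% and 0.0569% of the counts of a library. Of the 6629 remaining identifiers, 5956 matched a locus tag of the NCBI RefSeq annotation of build R64, from which symbols and coordinates were taken, and 673 were kept under their own identifier. Annotated gene lengths are multiples of 3 for 92.2% of genes, and run from start to stop codon with any intron included. Totals ran from 223189 to 1634021 counts per library, so 1 count stood for between 0.612 and 4.48 CPM (counts scaled to a common library total).

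Genes were kept with edgeR's filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 5090 genes. Counts were scaled by TMM, and all 9 libraries entered one fit with a coefficient per group. Comparisons were tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. Standard errors are the size of the log2 fold change divided by the square root of F, and CPM values are TMM-scaled. Adjusted p-values below come from this test unless another is named. Gene lists were tested with camera at a preset correlation of 0.01, over the 31 of 33 lists with at least 5 tested members, with Benjamini-Hochberg adjustment within a comparison. Camera with an estimated correlation was run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

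The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named YET3, its family members and the other genotype markers, the 12 largest changes in each direction among called genes whose libraries did not overlap, up to 4 members of each list with the smallest p-values, all sterol synthesis genes, and the neighbours of YET3 and HO. For overexpression against deletion it took 6 genes in each direction and 2 members per list. Genes named outside it are marked as chosen after their values were seen.

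The test was checked on simulated counts for the 5090 genes, drawn with the trended dispersion. The 2-fold and 4-fold changes were placed in genes with a mean of at least 20 CPM, so recovery of lower genes was not measured. In the simulated comparison of overexpression with control, 27.0% of genes changed 2-fold and 97.0% of genes changed 4-fold were recovered. The shares were 37.0% and 99.0% for deletion against control, and 31.0% and 98.0% for overexpression against deletion. In each, camera called the moved list and 0 of 20 unmoved lists. The simulated genes varied independently, so this does not check camera on lists whose genes move together between libraries. Counts of replicate pairs differed by more than sampling noise in every group, with a chi-square per degree of freedom between 1.58 and 19.1, so no pair was merged as 1 library deposited in duplicate. This does not show that the libraries are separate cultures.

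The alternatives fixed beforehand were DESeq2 size factors, the DESeq2 Wald test, no filter on low counts, a stricter filter of 20 CPM in 3 libraries, a fit of the 6 libraries compared, the replicate number as a block, the removal of the YET3 and HO rows, and each library left out in turn. A fit with a term for 3 libraries that stand apart, and a fit without them, were added after the data were seen.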

Results

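Transcript levels were measured by RNA sequencing in 3 yeast strains with 3 libraries each: a control, a strain overexpressing YET3 and a strain labelled as lacking YET3. YET3 encodes an endoplasmic reticulum membrane protein of the BAP31-related family, with YET1 and YET2. The series concerns sterol synthesis at organelle contact sites. Control libraries 1 to 3 held 701159, 1618016 and 223189 counts. Overexpression libraries 1 to 3 held 613961, 651410 and 464074 counts, and the libraries labelled YET3 deletion held 1634021, 657151 and 403613 counts.

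YET3 (YDL072C, build R64, chromosome IV, 329836 to 330447, coding length 612 bases) stood at 477.7 ± 1.29 CPM (SD, n = 3) in the control. It rose to 1877 ± 478 CPM (SD, n = 3) in the overexpression libraries, with 2261, 2029 and 1341 CPM in libraries 1 to 3. The log2 fold change was 1.97 (SE 0.30, adjusted p = 0.00627). The libraries labelled YET3 deletion kept YET3 counts, at 728, 328 and 640 CPM, and the mean of 565 ± 210 CPM (SD, n = 3) gave a log2 fold change of 0.24 against control (SE 0.295, adjusted p = 0.709). The row therefore goes against the deletion label if it counts the deleted part. If it counts sequence outside that part it checks nothing, and the sources used here do not say which. The YET3 call in overexpression ended without control 1, 2 or 3 (adjusted p = 0.0711, 0.0671 and 0.0630), at log2 fold changes of 1.97, 1.97 and 1.98. Without overexpression 3, deletion 1 and deletion 3, which lay apart from the other libraries, the log2 fold change in the libraries labelled YET3 deletion was -0.54 (adjusted p = 0.702; 0.231 to 0.999 over 14 alternatives), with 1 such library left.

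HO (YDL227C, chromosome IV, 46271 to 48031), the endonuclease gene that carries the marker in the control strain, was counted at 45.0, 28.2 and 57.1 CPM in the control libraries. It lay between 0 and 7.58 CPM in the other 6 libraries. It fell in overexpression (log2 fold change -3.24, SE 0.64, adjusted p = 0.0318) and stood at -3.37 in the libraries labelled YET3 deletion (SE 0.60, adjusted p = 0.149; 7.85e-04 to 0.852 over 14 alternatives). Its call in overexpression ended without control 1, 2 or 3 (adjusted p = 0.188, 0.0845 and 0.130) and without overexpression 1 or 2 (0.117 and 0.106). MET17, another name of MET15, had 0 counts in all 9 libraries, which allows up to 13.4 CPM in the shallowest library. LEU2 had 0 to 3 counts and URA3 0 to 2 counts per library. HIS3, which the labels also give as deleted, had 54 to 356 counts per library (134 to 383 CPM before TMM scaling), and which part of the gene its row counts is not given in the sources used here. The genes next to YET3 did not pass the test in either comparison with control. In overexpression AHK1 gave 1.19 (SE 0.35, adjusted p = 0.269) and BDF2 gave 0.78 (SE 0.34, adjusted p = 0.686). In the libraries labelled YET3 deletion AHK1 gave 1.31 (SE 0.34, adjusted p = 0.400) and BDF2 gave 0.76 (SE 0.34, adjusted p = 0.414).

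**Figure D1:**
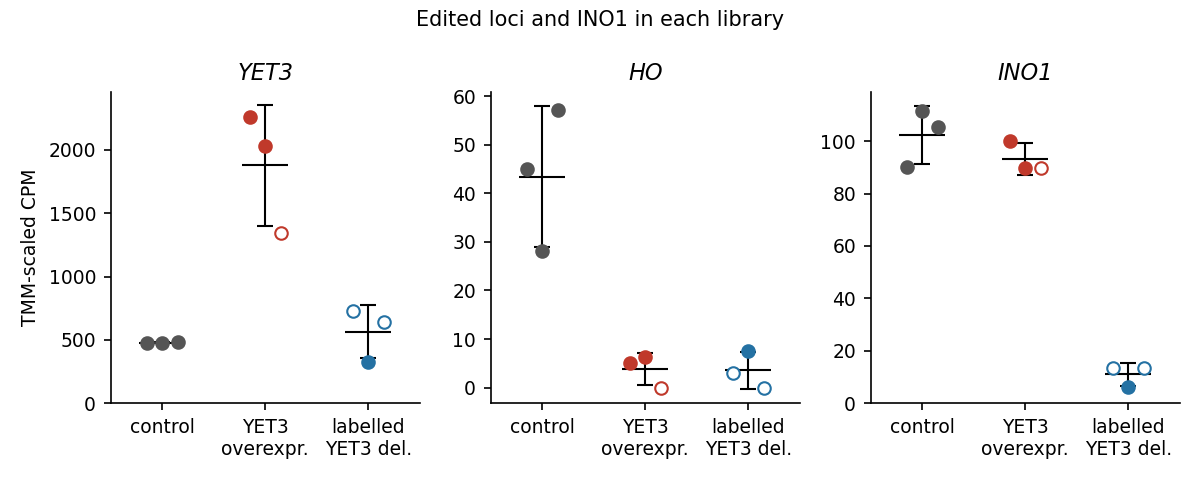
TMM-scaled CPM of YET3, HO and INO1 in each library of the 3 groups. Points are libraries, bars are the mean ± SD (n = 3), and open points are 3 libraries with a low share of counts at the ribosomal DNA rows. YET3 is highest in overexpression, from 1341 to 2261 CPM, HO is highest in the control, and INO1 is lowest in the libraries labelled YET3 deletion, from 6.07 to 13.6 CPM.

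The libraries also differed in a way the groups do not explain. Overexpression 3 and the libraries labelled deletion 1 and deletion 3 lay apart from the other 6 on the first principal component, which held 47.6% of the variance. Counts at the 5 YLR154W rows, in the ribosomal DNA, made up 0.162%, 0.267% and 0.111% of these 3 libraries. The share was between 0.817% and 2.42% in the other 6. No control library is among the 3. The comparisons were also made without these 3 libraries and with a term for them in the fit of all 9.

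**Figure D2:**
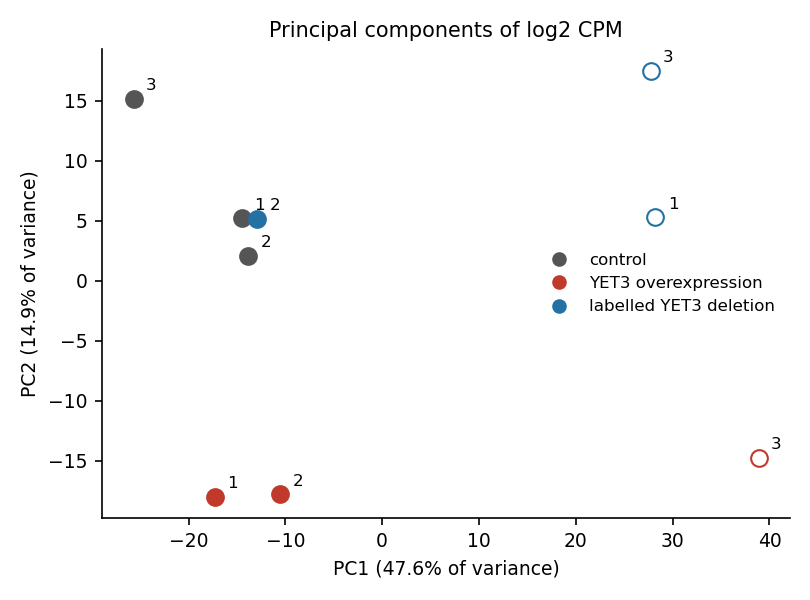
First and second principal components of log2 CPM over the 5090 genes tested, with the share of variance on each axis (47.6% and 14.9%). Each point is a library with its replicate number, and open points are the 3 libraries with under 0.5% of counts at the YLR154W rows, which lie to the right of the other 6.

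The first comparison asked what changes in cells that overexpress YET3. Genes of ergosterol synthesis rose, together with the cell wall mannoprotein genes TIR1, TIR3 and DAN1, the desaturase gene OLE1 and the heme synthesis gene HEM13. Of 5090 genes, 32 were higher and 11 lower than in the control, and the libraries of both groups did not overlap for any of the 43. Over all genes, 864 (17.0%) showed no overlap, where chance gives 10% if no other structure divides the libraries. Without the 3 libraries that lay apart, 90 genes were higher and 76 lower, with all 43 among them. The count of higher genes was 9 without control 1, 13 without control 2, 18 without control 3 and 19 without overexpression 2. The count of lower genes was 2, 2 and 3 without control 1, 2 and 3, and 4 and 2 without overexpression 1 and 2.

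The late part of the sterol pathway, from squalene synthesis to ergosterol, moved as a group. Of its 15 measured genes 7 rose over all genes tested and 12 when adjusted over the list alone, and all 15 had positive log2 fold changes (median 1.12). The list passed camera (adjusted p = 4.1e-28, and adjusted p = 5.89e-04 with an estimated correlation). The sterol desaturase gene ERG3 went from 157 ± 15.5 to 937 ± 152 CPM (SD, n = 3 each; log2 fold change 2.57, SE 0.23, adjusted p = 7.79e-05). The methyl sterol oxidase gene ERG25 went from 149.6 ± 32.8 to 750.4 ± 327 CPM (2.30, SE 0.37, adjusted p = 0.00895). ERG5 rose by 2.05, the squalene epoxidase gene ERG1 by 1.88, ERG28 by 1.74, ERG26 by 1.56 and ERG4 by 1.12 on the log2 scale, with adjusted p between 0.00741 and 0.0269. Of the 7 genes ERG3 passed with any library left out. Without control 1 the other 6 missed the threshold (adjusted p from 0.0711 to 0.216). ERG25, ERG28 and ERG4 missed it without control 2, together with ERG26 (0.0556 to 0.213), without control 3, together with ERG1 (0.0939 to 0.130), and without overexpression 2, together with ERG1 (0.0510 to 0.105). ERG11, the lanosterol demethylase gene, had a log2 fold change of 1.55 (SE 0.43) and missed the threshold (adjusted p = 0.207). Its log2 fold change was 1.92 without the 3 libraries that lay apart (adjusted p = 1.75e-10; up to 0.835 over 15 alternatives), and it passed without overexpression 3 alone (adjusted p = 0.00358). ERG2 at 0.90 and ERG6 at 0.72 also missed it (adjusted p = 0.668 and 0.783), and stood at 1.27 and 1.19 without the 3 libraries (adjusted p = 5.15e-07 and 7.74e-06; up to 0.992 over 15 alternatives). ERG2 passed without overexpression 3 alone (adjusted p = 0.0383). In overexpression 3 the genes ERG6, ERG2 and NCP1 lay below every control library. ERG6 stood at 151 CPM (control 292 to 391), ERG2 at 433 (472.5 to 611) and NCP1 at 245 (365 to 409). ERG11 stood at 315 CPM there, near the control range of 238 to 303. The rise of these genes therefore rests on overexpression 1 and 2. All 15 genes passed without the 3 libraries, and 13 with a term for them.

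**Figure D3:**
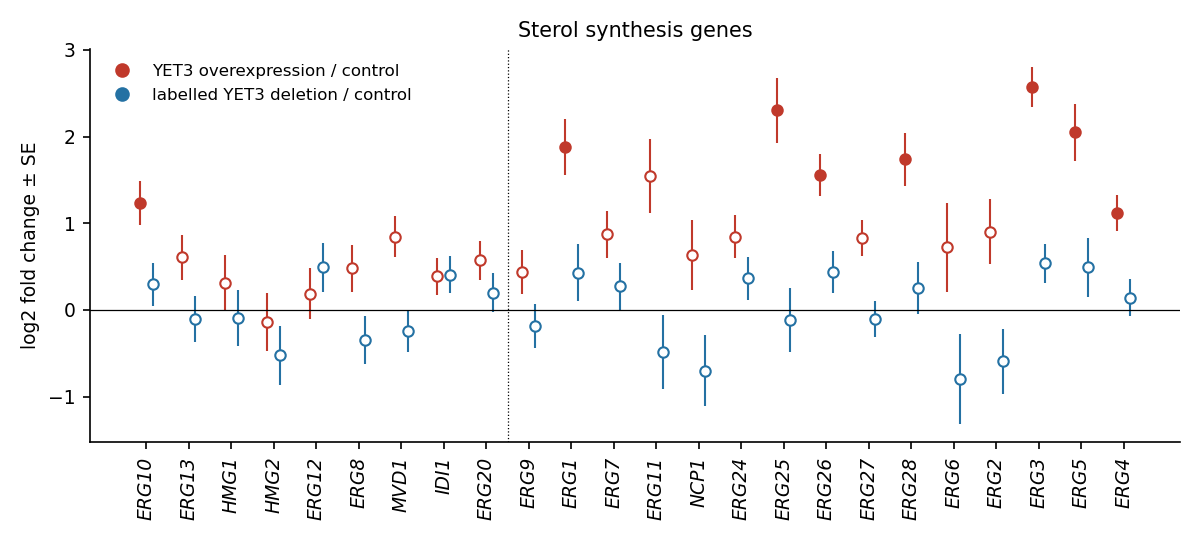
Log2 fold change ± SE of 24 sterol synthesis genes in pathway order, for overexpression and for the libraries labelled YET3 deletion, each against control (n = 3 libraries per group). Filled points passed an adjusted p of 0.05, and the dotted line parts the mevalonate genes from those after farnesyl pyrophosphate. In overexpression 8 points are filled, with ERG3 highest at 2.57, and none is filled in the other comparison.

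The early part of the pathway, from acetyl-CoA to farnesyl pyrophosphate, also moved as a group. The thiolase gene ERG10 rose (log2 fold change 1.23, SE 0.25, adjusted p = 0.0370), but its call ended without control 1, 2 or 3 (adjusted p = 0.281, 0.334 and 0.130) and without overexpression 1 or 2 (0.127 and 0.183). In the list 2 of 9 genes rose when adjusted over the list alone, and the median was 0.48. The list passed camera (adjusted p = 4.77e-04, and adjusted p = 0.0486 with an estimated correlation). MVD1 gave 0.84 and HMG1, which encodes an HMG-CoA reductase, 0.31 (adjusted p = 0.221 and 0.864). MVD1 passed without the 3 libraries that lay apart (0.854, adjusted p = 0.00498; up to 0.703 over 15 alternatives) and with a term for them (0.881, adjusted p = 0.01). UPC2, a transcription factor of sterol genes, had 16.1 ± 1.80 CPM in the control and 44.6 ± 14.0 in overexpression (SD, n = 3 each), a log2 fold change of 1.504 (SE 0.38) that missed the threshold (adjusted p = 0.131). It passed without the 3 libraries that lay apart (1.72, adjusted p = 3.29e-04; up to 0.640 over 15 alternatives) and without overexpression 3 alone (adjusted p = 0.0363). The list of sterol regulators did not pass (adjusted p = 0.0662).

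Genes of the hypoxic and heme list rose as a group, with 5 of 14 past the threshold over all genes and 7 when adjusted over the list alone (median 0.96). Camera gave an adjusted p of 1.33e-16, and adjusted p = 0.00147 with an estimated correlation. TIR1 went from 18.4 ± 7.41 to 386.8 ± 42.3 CPM (SD, n = 3 each; log2 fold change 4.38, SE 0.30, adjusted p = 1.31e-05) and TIR3 rose by 3.15 (SE 0.38, adjusted p = 0.00115). DAN1 had 5 counts over the 3 control libraries and 118 over the overexpression libraries, a ratio of 35.9 (95% counting interval 14.9 to 113; adjusted p = 0.00115). These mannoprotein genes belong to one family, and reads that they share cannot be assigned here. HEM13 rose by 1.93 (SE 0.24, adjusted p = 0.00154) and the cytochrome gene CYB5, named after its value was seen, by 2.00 (adjusted p = 0.00627). The call of CYB5 ended without control 1 (adjusted p = 0.0532) and control 2 (0.0765).

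Other genes with large rises were PBI1, with 15 counts in the control and 617 in overexpression (log2 fold change 5.97, SE 0.49, adjusted p = 3.47e-05, and 6.75 without control 2), and YPR145C-A (4.10, SE 0.38, adjusted p = 7.79e-05). HES1, of the oxysterol-binding protein family, had 2 control counts against 38, a ratio of 28.9 with a 95% counting interval from 7.46 to 247 (adjusted p = 0.00627). The call of HES1 ended without control 1 (adjusted p = 0.0598) and without control 2 (0.168). ATF2, which encodes an acetyltransferase, rose by 2.46 (SE 0.37, adjusted p = 0.00627), and its call ended without control 1 (adjusted p = 0.0711). HES1 and ATF2 were the 2 members past the threshold of 23 in the sterol ester, uptake and transport list, which passed camera (median 0.22, adjusted p = 0.00383, but adjusted p = 0.0606 with an estimated correlation). In the fatty acid list OLE1 rose by 2.03 (SE 0.30, adjusted p = 0.00627) and the elongase gene ELO1 fell by 1.44 (SE 0.26, adjusted p = 0.0197), with 13 of 15 not past the threshold. Another 6 of the 15 were called higher without the 3 libraries that lay apart, FAS1 (0.892, adjusted p = 4.26e-05; up to 0.498 over 15 alternatives) and MGA2 (0.846, adjusted p = 0.00858; up to 0.608) among them. With a term for the 3 libraries 5 of these 6 were called, again with FAS1 and MGA2 (adjusted p = 0.00385 and 0.0192). The call of OLE1 ended without control 1 (adjusted p = 0.0659), and that of ELO1 without control 1 or 2 (0.118 and 0.161) and overexpression 1 or 2 (0.0982 and 0.105). The list median was 0.40 (adjusted p = 0.0116, and adjusted p = 0.0945 with an estimated correlation). None of 17 unfolded protein response genes passed (list median 0.28, adjusted p = 0.0287, but adjusted p = 0.123 with an estimated correlation), and the list did not pass without control 1 (adjusted p = 0.0530) or overexpression 1 (0.0938). With the 3 libraries that lay apart left out, KAR2 was called higher (0.630, adjusted p = 0.00805; up to 0.992 over 15 alternatives) and ERV2, named after its value was seen, lower (-0.605, adjusted p = 0.0372). Neither was called with a term for the 3 libraries. The heat shock gene HSP26 rose by 1.96 (SE 0.26, adjusted p = 0.0022), while the other 21 genes of its stress list did not pass and the list did not either (adjusted p = 0.589).

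The largest fall was that of ZPS1, from 305 ± 13.5 to 19.2 ± 2.38 CPM (SD, n = 3 each; log2 fold change -4.00, SE 0.32, adjusted p = 3.47e-05). ICL1, the isocitrate lyase gene of the glyoxylate cycle, fell by 2.52 (SE 0.34, adjusted p = 0.00293). CWP1, a cell wall mannoprotein gene, fell by 2.38 and IDP2, a cytosolic isocitrate dehydrogenase gene, fell by 1.92 (adjusted p = 0.0452 and 0.0318). OM14, YAT2, RTC2, YNL194C and the methionine permease gene MUP1 fell by between 1.08 and 1.39 (adjusted p between 0.0107 and 0.0481). The calls of these 5 genes each ended without control 1, 2 or 3 and without overexpression 1 or 2 (adjusted p from 0.0537 to 0.322). CWP1 was not called without control 1, 2 or 3 (adjusted p = 0.188, 0.168 and 0.188) or overexpression 2 (0.208), and IDP2 without any of the 6 libraries (0.0616 to 0.208). The mean in the libraries labelled YET3 deletion was also below the control for ICL1 (117 against 282 CPM), IDP2 (22.3 against 56.0) and CWP1 (316 against 588). The same held for OM14 (619 against 1049), YAT2 (96.6 against 160) and YNL194C (101 against 164). For CWP1 only deletion 1 and deletion 3, which lay apart, were low (177 and 234.5 CPM). Deletion 2 stood at 535.5 CPM, within the control range of 513 to 637. With a term for the 3 libraries that lay apart CWP1 gave 0.00388 in the libraries labelled YET3 deletion, and ICL1 -1.49. RTC2 and MUP1 were nearer the control (88.9 against 112, 256 against 268). ZPS1 and ELO1 were above it (347.5 against 305, 152 against 123). None of these genes was called in that comparison with all 9 libraries. Of 21 sulfur and methionine genes MUP1 passed the threshold over all genes, and 4 fell when adjusted over the list alone (median -0.49, adjusted p = 7.04e-05, and adjusted p = 0.0486 with an estimated correlation). Without the 3 libraries that lay apart MET32 (-1.90), STR3 (-1.80), MMP1 (-1.73) and MET2 (-1.16, named after its value was seen) were called as well (adjusted p from 0.00197 to 0.0293), as they were with a term for the 3 libraries (0.00753 to 0.0456). All 14 genes of the M/G1 cell cycle list had negative log2 fold changes, with 0 past the threshold over all genes and 1 lower when adjusted over the list alone (median -0.58, adjusted p = 5.94e-06, but adjusted p = 0.147 with an estimated correlation). Of the 14, 2 were called lower without the 3 libraries and 0 with a term for them. The other 23 of 31 lists did not pass.

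The second comparison asked what changes in the strain labelled as lacking YET3, and its directions rest on libraries whose YET3 counts do not show the loss. INO1, the inositol phosphate synthase gene (YJL153C, chromosome X, 134332 to 135933), fell from 102 ± 11.1 CPM (SD, n = 3) to 13.6, 6.07 and 13.3 CPM in libraries 1 to 3 (log2 fold change -3.16, SE 0.29, adjusted p = 4.53e-04). It was the 1 gene called lower, and 0 were called higher, by edgeR's quasi-likelihood test, while 604 genes had an unadjusted p under 0.05. The DESeq2 Wald test called 5 lower and 0 higher, with 497 at an unadjusted p under 0.05. The call of INO1 held in all 15 alternatives (adjusted p up to 0.00670). The size of its fall is uncertain, since 3 counts stand for 1.836, 4.565 and 7.433 CPM in libraries 1 to 3 before TMM scaling. Without the 3 libraries that lay apart INO1 stood at -4.05, from the few counts of deletion 2 alone, which was assumed to vary like the other groups. The libraries did not overlap for 988 genes (19.4%), where chance gives 10% if no other structure divides the libraries. Deletion 1 and deletion 3 lay apart and no control did, so the excess cannot be credited to the strain alone.

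The phospholipid list, drawn up around Ino2 and Ino4 and holding the regulator genes INO2, INO4 and OPI1 as well, fell in the libraries labelled YET3 deletion. Of its 17 genes 15 had negative log2 fold changes (median -0.47), 1 fell over all genes and 4 fell when adjusted over the list alone. Camera gave an adjusted p of 1.38e-07, and adjusted p = 0.0375 with an estimated correlation. Beside INO1 these were the methyltransferase gene OPI3 at -1.12 (SE 0.22, adjusted p = 0.288 over all genes), INO4 at -1.08 (SE 0.23, adjusted p = 0.288) and the repressor gene OPI1 at -0.93 (SE 0.24, adjusted p = 0.400). OPI3 passed without the 3 libraries that lay apart (-1.08, adjusted p = 0.00629) and with the DESeq2 Wald test (adjusted p = 0.00335; up to 0.852 over 15 alternatives), and INO4 passed with that test (adjusted p = 0.0311). Ribosome biogenesis genes had a median of 0.35 with 0 of 30 past the threshold (adjusted p = 7.5e-04, but adjusted p = 0.0563 with an estimated correlation). Without deletion 2 the list did not pass (adjusted p = 0.139). The sterol lists did not pass (adjusted p = 0.841 for the late part and 0.880 for the early part). ERG3 gave 0.54 (SE 0.225), ERG11 -0.49 (SE 0.43), ERG2 -0.59 (SE 0.38) and ERG6 -0.80 (SE 0.52), with adjusted p between 0.400 and 0.590, and ERG11, ERG2 and ERG6 turned positive with a term for the 3 libraries that lay apart (0.36, 0.16 and 0.22). The other 29 of 31 lists did not pass.

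Across the 5090 genes, which are not independent replicates, the log2 fold changes of both comparisons against the shared control correlated with Pearson's r = 0.574. In 50 simulations all libraries were drawn anew from the control means, with a spread estimated over all groups. There, 2 unchanged groups set against shared simulated controls gave 0.498 (0.479 to 0.518 in 95% of simulations). The covariance was 0.140 against a simulated 0.0701, a difference of 0.0698. The sign matched in 73.8% of genes, against 66.5% in the simulation. No called gene was shared, where independent lists would share 0.00216 lower genes, and with 1 gene called in the libraries labelled YET3 deletion this says little. But 2 genes were called lower in both comparisons without the 3 libraries that lay apart: ICL1 (-2.73 and -1.36) and ECM13 (-1.44 and -1.97), the latter named after its value was seen. These 2 were among 76 and 5 lower genes, where independent lists would share 0.0722, and rest on the same controls and 1 library labelled deletion. With a term for the 3 libraries 0 were shared. With 3 controls no split leaves 2 in each part, so the part of the shared controls was judged by the simulation alone. The simulation already holds shared controls, so they explain the excess only if real controls varied more than simulated ones. Control pairs gave a chi-square per degree of freedom of 1.58 to 4.56. Pairs of the libraries labelled YET3 deletion gave 8.97 to 19.1, and overexpression pairs 2.57, 14.3 and 18.8. These values also depend on depth, but they argue against real controls that varied more than the spread over all groups. Libraries from both groups are among the 3 that lay apart, and this structure was not simulated.

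The third comparison set overexpression directly against the libraries labelled YET3 deletion, so its directions also rest on libraries whose YET3 counts do not show the loss. Of 5090 genes 34 were higher and 3 lower in overexpression, and the libraries did not overlap for 483 genes (9.49%), where chance gives 10%. YET3 was higher by 1.73 (SE 0.30, adjusted p = 0.0182), and by 2.71 without the 3 libraries that lay apart (adjusted p = 4.73e-10; up to 0.112 over 14 alternatives). Leaving these 3 out keeps 1 library labelled deletion, so this p, and each call without them in this comparison, takes the spread from the other groups. The late sterol genes were higher, with 4 of 15 past the threshold over all genes and 14 when adjusted over the list alone (median 1.45, adjusted p = 1.15e-29, and adjusted p = 5.02e-04 with an estimated correlation). Over 15 alternatives the list median ran from 1.07 to 1.46, which overlaps the 1.06 to 1.27 of overexpression against control. ERG25 gave 2.42 (SE 0.37, adjusted p = 0.00754), ERG3 2.03 (SE 0.22, adjusted p = 4.8e-04), ERG5 1.56 and ERG28 1.49 (adjusted p = 0.0377 and 0.0418). UPC2 was higher by 1.92 (SE 0.39, adjusted p = 0.0416). Of 14 hypoxic and heme genes 5 were higher (median 1.37, adjusted p = 8.26e-22, and adjusted p = 6.62e-04 with an estimated correlation). TIR1 was higher by 5.16 (SE 0.32, adjusted p = 3.23e-06) and OLE1 by 2.16 (SE 0.30, adjusted p = 0.00373). DAN1 had 118 counts against 3, a ratio of 63.4 with a 95% counting interval from 21.2 to 312, and the 3 counts were all in deletion 1. INO1 was higher by 3.02 (SE 0.30, adjusted p = 1.62e-04), and by 3.93 without the 3 libraries that lay apart, while INO4 was higher by 1.14 (SE 0.23, adjusted p = 0.0368), and the phospholipid list passed (median 0.22, adjusted p = 2.75e-06, and adjusted p = 0.0291 with an estimated correlation). ZPS1 at -4.16, ELO1 at -1.71 and the glucanase gene SCW11 at -1.45 were the 3 lower genes (adjusted p = 1.91e-05, 0.00673 and 0.0374). Among the 6 libraries that did not lie apart 59 were higher and 17 lower. Leaving out overexpression 1, 2 or 3 gave 20, 15 and 57 higher genes, and leaving out deletion 1 or 3 gave 16 and 14. The lower genes numbered 1 without overexpression 2 and 17 without overexpression 3. The call of YET3 ended without overexpression 1 or 2 or deletion 3 (adjusted p = 0.0633, 0.0987 and 0.0764), that of ERG25 without deletion 1 or 3 (0.0615 and 0.0831) and that of ELO1 without overexpression 2 (0.0520). ERG5 and ERG28 were not called without overexpression 2 or any of deletion 1, 2 and 3 (0.0862 to 0.136). UPC2 and SCW11 were not called without overexpression 1 or 2 or deletion 1 or 3 (0.101 to 0.291), nor among the 6 libraries that did not lie apart (0.104 and 0.103). INO4 was not called without overexpression 1 or 2 or deletion 1, 2 or 3 (0.0676 to 0.186). Of 31 lists 10 passed camera, and 4 of them with an estimated correlation: both sterol lists, the hypoxic and heme list and the phospholipid list. The rest included the genotype markers (camera adjusted p = 0.0261), whose 1 called gene was YET3 itself, so that list is no separate result. Sterol regulators, sterol ester, sulfur, M/G1 and a-specific mating genes made up the remainder (camera adjusted p from 2.34e-04 to 0.0499).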

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

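The term for the 3 libraries that stand apart and the fit without them were chosen after the result was seen. Across the 15 alternatives run for each, these gene lists kept their direction and their side of the threshold: late sterol genes (median 1.06 to 1.27 in overexpression against control), early sterol genes, hypoxic and heme genes, and the phospholipid genes in the libraries labelled YET3 deletion (median -0.65 to -0.43). PBI1, TIR1, TIR3, DAN1, YPR145C-A, ERG3, HEM13, HSP26, ZPS1 and ICL1 in overexpression against control, and INO1 in the libraries labelled YET3 deletion, passed in all 15.

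Counts of called genes moved. With the term for the 3 libraries, 72 genes were higher and 41 lower in overexpression against control, and 89 higher and 17 lower in overexpression against deletion. Without the 3 libraries the counts were 90 and 76, and 59 and 17, with 5 lower in the libraries labelled YET3 deletion. The DESeq2 Wald test called 18 lower genes in overexpression against control, 5 lower in deletion against control, and 54 higher and 5 lower in overexpression against deletion. A fit of 6 libraries called 3 lower genes in deletion against control and 13 higher in overexpression against deletion. The cause of these moves was not tested. Leaving out one library gave 9 to 35 higher and 2 to 11 lower genes in overexpression against control, 14 to 57 higher and 1 to 17 lower in overexpression against deletion, and 0 higher and 1 lower in deletion against control each time, from fewer samples.

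The replicate numbers showed no clear pairing of the samples. Correlations of same-numbered libraries ran from -0.46 to 0.51, 3 of 9 were over 0.1, and 3 of 9 libraries correlated best with their own number. But the difference of the 3 libraries that stand apart was not removed first, and the values follow it. Overexpression 3 gave 0.544 with deletion 1, and overexpression 1 gave 0.594 with deletion 2. A pairing by number therefore cannot be excluded. The replicate block left 4 lower genes in overexpression against control and 23 higher.

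In deletion against control, YET3 turned to -0.54 and ERG11 to 0.17 without the 3 libraries, and ERG2, ERG6 and ERG11 turned to 0.16, 0.22 and 0.36 with the term for them. None of these passed, and the cause was not tested. Among single genes and lists, 38 values newly passed and 50 no longer passed under the other settings, the fit without the 3 libraries included, while 3 newly passed and 135 no longer passed with one library left out. At this depth 2-fold changes were mostly missed in the simulated data, with 27.0% recovered in overexpression against control.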

Other observations

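The tests of gene length, ribosome genes, sequencing depth, HO, the retained YET3 sequence, the sterol list without the 3 libraries, Zap1 and the other splits of the samples were chosen after the result was seen, as were the fits that treat the 3 libraries that stand apart and the interval used to weigh low oxygen.

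With these 3 libraries left out, 7 genes beside ICL1 are named here after their values were seen in overexpression against control, for their known part in the use of carbon sources other than glucose. ICL1 fell by 2.73 (SE 0.26, adjusted p = 1.0e-08), and the log2 fold change was -1.64 for the malate synthase gene MLS1 (adjusted p = 0.00104), -2.29 for the succinate-fumarate carrier gene SFC1 (adjusted p = 2.61e-04), -1.42 for the lactate transporter gene JEN1 (adjusted p = 7.92e-04) and -2.18 for the acetate transporter gene ADY2 (adjusted p = 0.00366). PCK1 and FBP1, of gluconeogenesis, stood at -1.40 and -1.16 (adjusted p = 0.0042 and 0.0372). FBP1 missed the threshold with a term for the 3 libraries (adjusted p = 0.0772), and ADH2 stood at -1.83 without them and did not pass (adjusted p = 0.153). With all 9 libraries ICL1 passed, MLS1, SFC1, JEN1, ADY2, PCK1 and FBP1 did not (adjusted p from 0.131 to 0.767), and ADH2 had too few counts to test. In the libraries labelled YET3 deletion ICL1 was also lower in that setting (-1.36), from a single remaining library. INO1, OPI3 and, named after their values were seen, ECM13 and MOG1 fell there as well. The carbon genes were lower in these libraries with a term for the 3 libraries too. SFC1 gave -1.83, PCK1 -1.73, ICL1 -1.49, MLS1 -1.15, FBP1 -1.03, JEN1 -0.873 and ADY2 -0.542, with none called (adjusted p from 0.102 to 0.999). In overexpression that fit gave PCK1 -1.28 and FBP1 -1.04, but SFC1 -2.41 and ICL1 -2.61. Lower values of these genes were therefore not particular to overexpression, though both comparisons rest on the same controls. No list of such genes was fixed beforehand, so they are single genes and not a test of a pathway.

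Overexpression 3 and the libraries labelled deletion 1 and 3 stood apart from the other 6. Spearman's rho across genes between the log2 difference of the 3 libraries and gene length from start to stop codon was -0.0298, and 2 of the 3 totals lay within the range of the other 6, which argues against length and depth as its cause. The list of stress-induced genes had a median difference of -0.0676 (95% bootstrap interval -0.40 to 0.09; 2 of 22 called higher and 6 lower), which argues against a shared shift of 0.5 in these genes and not against other states of the cultures. A growth state stays open: ribosomal protein genes held 29.2% to 29.5% of counts in the 3 libraries and 25.7% to 28.3% in the other 6, but their median difference was -0.0362 (95% bootstrap interval -0.172 to 0.0875) and that of ribosome biogenesis genes 0.0862 (-0.248 to 0.423), with members called both ways. For GC content from start to stop codon rho was -0.292, short of the 0.3 set beforehand, but over the last coding bases and the sequence downstream, a measure not part of that test, it was -0.421, so a library preparation difference tied to base composition may contribute and stays open.

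YET3 counts in the libraries labelled YET3 deletion have 3 explanations to weigh. HO lay below every control library in 3 of 3, which argues against these being control libraries. The longest exact stretch that YET3 shares with YET1 or YET2 is 13 bases, too short for shared reads. Reads from YET3 sequence left outside the deleted part may explain the counts: the log2 fold change was 0.244, no row counts the deleted part alone, and this cannot be told apart from a strain that kept the gene.

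Late sterol and cell wall mannoprotein genes rose together in overexpression, and without the 3 libraries that stand apart the median of the late sterol list was 1.27, which argues against those libraries as the cause. Low oxygen stays open: the oxygen-repressed genes ANB1, COX5B and CYC7 went both ways, with log2 fold changes of 1.13, 0.10 and -0.47 (mean 0.252, 95% interval across the 3 genes -1.76 to 2.27), and AAC3 had too few counts to test. The choice of interval decides this: one from the standard errors of the 3 genes, -0.146 to 0.65, lies under the 1 set beforehand, but leaves out that the genes go both ways. A candidate explanation is Upc2 and Ecm22 acting through sterol regulatory elements, since TCGTATA lay within 500 bases upstream of 8 of 31 higher genes (25.8%) and of 6.77% of the other 4979 (Fisher's exact test, two-sided, odds ratio 4.79, 95% interval 1.84 to 11.2, p = 9.03e-04). Without the sterol synthesis genes it lay upstream of 4 of 23 (Fisher's exact test, two-sided, odds ratio 2.87, p = 0.0692), so outside that pathway the excess did not pass.

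A hypothesis that Zap1, the zinc-responsive activator, is less active in overexpression came from the fall of ZPS1 and the values of ZRT1 and ADH4. The median of 9 other Zap1 targets was -0.0697 (95% bootstrap interval -0.24 to 0.44, camera adjusted p = 0.817), which argues against a shared fall of these 9. ZRT3, ZRC1, ZRG17, ZRT2 and PEP4 were negative (-0.536 to -0.0697), and IZH1, IZH2, FET4 and MCD4 positive (0.157 to 0.884). ZPS1, ZRT1 and ADH4 were left out because their falls prompted the hypothesis, so the test cannot exclude a fall of some targets. ZRT1 gave -0.91 (adjusted p = 0.294), and -1.06 without the 3 libraries that stand apart (adjusted p = 9.54e-05).

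The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In overexpression against control 1 of the 10 splits, the real one, gave as many as 43 genes, and the highest other gave 0. In deletion against control 1 of 10 gave as many as the real 1, and the highest other gave 0. In overexpression against deletion 2 of 10 gave as many as the real 37. The other split, overexpression 1 and 2 with deletion 2 against the 3 libraries that stand apart, called 1523 genes and points to a structure of the samples. With a term for it the comparison called 89 higher and 17 lower genes.

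The 2 appended rows for HTB2 and HHT2 held 240 to 451 and 74.6 to 139 CPM, which was 74.6% to 91.6% and 7.0% to 14.1% of the counts in the first rows.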
